A study of Mus musculus with 4 samples.

How the data were processed

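RNA was isolated from mouse quadriceps with Trizol and RNeasy columns, converted to biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The series held 4 arrays, 2 from mdm mutant mice and 2 from wild type mice. Groups were taken from the genotype label of each sample. The sample titles mark the mutant mice as Ttn+ and the wild type mice as Ttn-, and the descriptions settle that the plus sign stands for the mutation. The replicate numbers only name mice within a group, in deposition order, and were never used to pair mice. The array model and the probe set definition are not given in the sources used here.

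The deposited values were log2 expression values made by the authors with RMA, per the submitters' processing notes, which name no version. RMA corrects background, quantile normalizes probes across arrays and summarises each probe set on the log2 scale. In the table the 4 columns also held the same sorted values, with 26 of 16553 ranks differing by over 1e-06. The arrays had therefore been brought to 1 common distribution at the level of probe sets, so a shift of most genes in the same direction would not be visible. Because of this, centring on the median or quantile normalizing again moves almost nothing. The table held no detection calls, so no level was called present or absent. Sequencing depth has no counterpart here: the number of arrays limits the precision.

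Of 16553 probe sets, 61 array controls were left out of the tests. Of the 16492 tested, 15270 had 1 gene symbol, none had several and 1222 had no gene listed in the platform annotation used, so these stay unnamed here. Symbols were updated by Entrez identifier from a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for gene order around Ttn. In all 15267 distinct genes were named, 3 of them measured by more than 1 probe set. Such a gene was represented by the probe set with the highest mean over all arrays.

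Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), mdm mutant minus wild type, with no covariates, and Benjamini-Hochberg adjustment over the 16492 probe sets. A probe set was called at an adjusted p under 0.05. The fit had a prior of 3.35 degrees of freedom and 5.35 in total per gene. Gene lists were tested with limma's camera (2-sided, preset inter-gene correlation of 0.01) on 1 probe set per gene, adjusted over the 29 lists with at least 5 measured genes. The alternative tests were camera with a correlation estimated from the residuals, fry and camera on ranks. With an estimated correlation no list was called, and with 2 residual degrees of freedom that estimate is itself imprecise. Members of a list were counted as past the test across all probe sets and, beside it, when adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

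The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes were named by that rule if they were Ttn or Sln, if they were among the 12 largest rises or 12 largest falls of called genes whose groups did not overlap, if they had 1 of the 4 smallest p-values in a list, if they were sex-linked genes, or if a stated count of 5 or fewer covered them. Predicted genes and unnamed cDNAs were left out of the largest rises and falls, which removed 0 from the rises and 1 from the falls. Genes named outside the rule are said to be so. The lists were titin, Z-disc and M-band partners, calcium handling, slow and fast fibre genes, embryonic muscle, denervation, energy metabolism, protein turnover, stress, membrane repair, inflammation, matrix, cell cycle, clock and immediate early genes, and markers of other cell types a quadriceps sample can hold.

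The fit was tested on simulated data with 16492 genes in 5 draws, with 200 genes changed in each. In that simulation of the comparison, 95.2% of genes changed by 0.5 on the log2 scale were recovered, 100% of those changed by 1 and 99.7% of those changed by 2, with 17 false calls per draw on average. The simulated genes had independent noise and do not include differences between animals that many genes share. Fewer genes were changed than the 2115 called in the measured data. Measured genes with a larger spread, such as Tnni1, did not pass at a difference over 1, so these shares do not carry over to such genes.

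Alternatives were removal of the dimmer 50% of probe sets, centring on medians, repeated quantile normalization, eBayes with trend and robust on, no variance moderation, the mean of all probe sets of a gene, each mouse left out in turn, and other thresholds. For lists they were also the other list tests and removal of genes held by more than 1 list. Centring on the 18 hybridization control probe sets (bioB, bioC, bioD and cre) was added after the data were seen. An alternative with log2(value + 16), meant for linear values, was not run because the values were already on a log scale. With a mouse left out, the lone mouse of its group is assumed to vary like the other group.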

Results

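Gene expression was measured in quadriceps muscle of 4 mice with Affymetrix arrays, 1 array per mouse. The mdm mutant group held 2 mice of the strain B6C3Fe a/a-Ttnmdm/J that carried a mutation in titin, the giant protein that spans the sarcomere and acts as its molecular spring. The wild type group held 2 mice labelled as titin wild type. The labels give each mouse its own number, so the 2 arrays of a group are separate animals. The table listed 16553 probe sets per array, of which 61 were array controls and 16492 were tested. The values were log2 RMA values between 5.42 and 14.98, with a median of 7.28 on every array. Their number, 2 per group, limits the precision. Differences are mdm mutant minus wild type on the log2 scale, given ± the standard error from limma, and levels are given ± SD, with n = 2 mice per group throughout. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over all probe sets tested.

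The comparison asked which transcripts differ in dystrophic mdm muscle, and the series title names sarcolipin and inflammatory processes. Sarcolipin (Sln, Entrez 66402), a small membrane protein of the sarcoplasmic reticulum that inhibits the calcium pump, was the gene with the largest rise. Its level was 13.66 ± 0.10 in mdm mutant and 8.05 ± 0.05 in wild type muscle, a difference of 5.61 ± 0.07 or 48.7-fold (95% interval 5.43 to 5.78 on the log2 scale, adjusted p = 2.96e-05). Without variance moderation its difference was the same with an adjusted p of 0.103. Lists of embryonic muscle genes, immediate early genes, and macrophage and neutrophil markers shifted upward in mdm mutant muscle, and lists of mitochondrial energy supply and sugar use shifted downward. These calls used camera with a preset correlation, and with an estimated correlation none held (smallest adjusted p = 0.346). Titin itself (Ttn, Entrez 22138) was measured by 1 probe set and read 12.67 ± 0.02 in mdm mutant and 12.62 ± 0.05 in wild type muscle. The difference of 0.05 ± 0.05 (95% interval −0.08 to 0.19, adjusted p = 0.564) did not pass the test. The position of this probe set relative to the mutation is not given in the sources used here, so its level checks nothing about the labels.

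Across the array, 2115 probe sets (12.8%) passed the test, 1066 higher and 1049 lower in mdm mutant muscle. Of these, 119 differed at least 2-fold, 89 upward and 30 downward, and 23 rose but 1 fell at least 4-fold. In all 2115 the values of the groups did not overlap, which held for 60.9% of all probe sets tested against 33.3% by chance for 2 against 2 mice. Overlapping values cannot reach a call with 2 mice per group at this threshold, so the lack of overlap among the calls adds no support. The count rested on all 4 animals: it was 1182 without mdm mutant 1, 573 without mdm mutant 2, 490 without wild type 1 and 516 without wild type 2. Without variance moderation, which leaves 2 residual degrees of freedom per gene, 1 probe set passed and 3286 had an unadjusted p under 0.05. The 1 probe set was not among the 2115, of which 0 passed under this setting. With the arrays centred on the hybridization control probe sets, an alternative chosen after the data were seen, 2829 were higher and 603 lower, in place of 1066 and 1049. These controls read 11.01 and 10.99 on average in the mdm mutant mice and 11.10 and 11.12 in the wild type mice, and centring on them raised the median difference of all probe sets from −0.02 to 0.09. The controls did not share 1 shift. The dimmer bioB and bioC probe sets differed by −0.27 to −0.14, bioD by −0.13 to 0.03 and cre by 0.01 to 0.07. A constant per array does not correct such a pattern, so all results under this setting rest on that average. Of the 137 named genes called, 55 were called with any 1 mouse left out.

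The 12 largest rises included genes of muscle development, stress and inflammation. Myh3 and Myh8, the embryonic and perinatal myosin heavy chains, rose by 4.59 ± 0.16 (24.0-fold) and 2.68 ± 0.05, and Myl4, the embryonic myosin light chain, by 3.04 ± 0.13. Myog, a transcription factor of myoblast differentiation, rose by 2.61 ± 0.12. Ankrd1, an ankyrin repeat protein that binds titin, rose by 4.50 ± 0.13 (22.6-fold). The chemokine Cxcl10 rose by 3.20 ± 0.30 and galectin 3 (Lgals3), abundant in macrophages, by 2.60 ± 0.19. The cell cycle inhibitor Cdkn1a rose by 2.58 ± 0.12, the small GTPase Rrad by 2.91 ± 0.09, the copine Cpne2 by 2.86 ± 0.08 and the matrix protein Cilp by 2.69 ± 0.06. Adjusted p-values of these 12 genes, sarcolipin included, lay between 2.96e-05 and 0.00750, and all 12 passed the test with any 1 mouse left out.

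The 12 largest falls included genes of fuel use. Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell most (−2.18 ± 0.23, 4.52-fold). The uncoupling proteins Ucp1 and Ucp3 (−1.63 ± 0.37 and −1.42 ± 0.10), the muscle nicotinamide riboside kinase Nmrk2 (−1.92 ± 0.23) and Chac1, an enzyme that breaks down glutathione (−1.97 ± 0.25), also fell. So did the kinase Map2k6 (−1.55 ± 0.13), the receptor partner Ramp1 (−1.52 ± 0.11), the phosphatase inhibitor subunit Ppp1r1a (−1.38 ± 0.12) and Grb14, an inhibitor of the insulin receptor (−1.33 ± 0.06). The glucose 6-phosphate transporter Slc37a4 (−1.25 ± 0.06), the potassium channel subunit Kcng4 (−1.22 ± 0.18) and Mlf1 (−1.20 ± 0.09) completed the group. Ucp1 also stands in the list of adipocyte markers, so its fall need not be one of muscle fibres. It read 6.64 and 6.49 in the mdm mutant mice and 8.80 and 7.60 in the wild type mice. Of these 12 genes, 7 passed the test with any 1 mouse left out. Pdk4 and Chac1 did not pass without wild type 2 (adjusted p = 0.0511 and 0.0604), Nmrk2 did not without mdm mutant 2 (adjusted p = 0.0575), and Ucp1 and Kcng4 did not without mdm mutant 1 or mdm mutant 2, with adjusted p up to 0.176 and 0.0763.

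**Figure D1:**
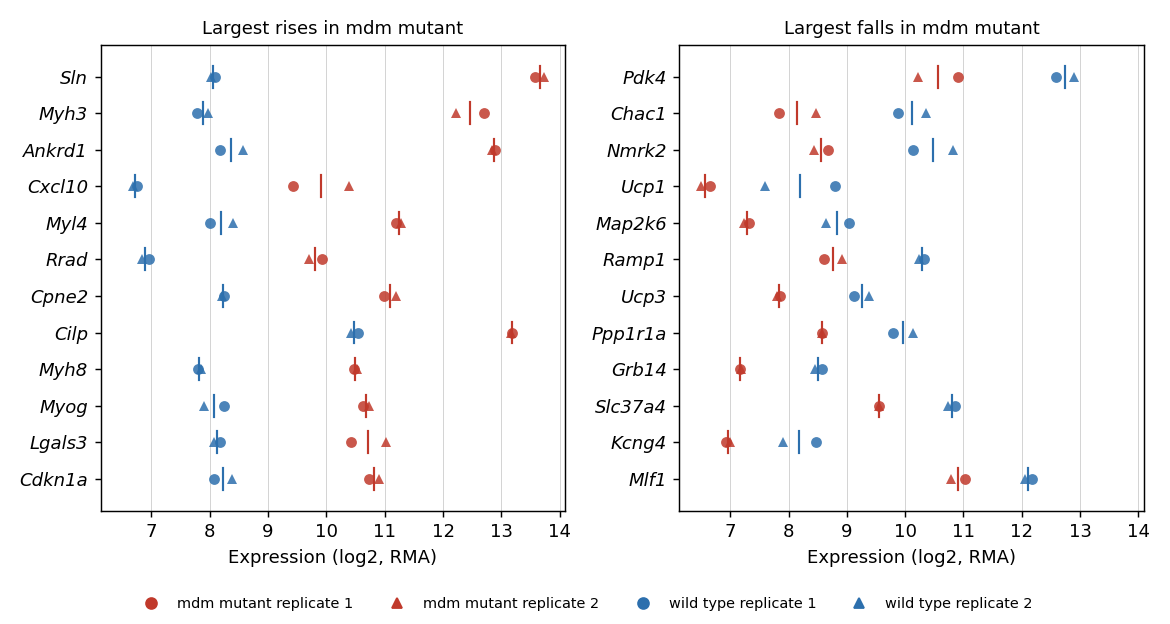
Expression of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in mdm mutant against wild type quadriceps. The horizontal axis is the log2 RMA value, each symbol is 1 mouse and each vertical bar is a group mean. Sln read 13.58 and 13.73 in the mdm mutant mice and 8.09 and 8.01 in the wild type mice.

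Genes of embryonic muscle and regeneration rose as a group. Among its 24 measured genes, 16 rose, 1 fell and 7 did not pass the test (18 up and 2 down adjusted over the list alone), with a median difference of 0.75 (adjusted p = 6.92e-13 by camera, adjusted p = 0.346 with an estimated correlation). Besides Myh3, Myh8, Myl4 and Myog, the fusion proteins Mymx and Mymk and the myogenic factors Myod1 and Myf5, picked after the values were seen, rose by 2.28 ± 0.11, 1.33 ± 0.12, 1.02 ± 0.11 and 0.95 ± 0.08. The gene that fell was Actc1, cardiac actin (−0.45 ± 0.09). The denervation response list, which shares Myog, Chrng and Ncam1 with that list, had 18 measured genes, of which 10 rose, 1 fell and 7 did not pass the test (10 up and 1 down adjusted over the list alone, adjusted p = 1.19e-05 by camera, adjusted p = 0.351 with an estimated correlation). The acetylcholine receptor subunits Chrng and Chrna1 rose by 1.03 ± 0.06 and 1.10 ± 0.07, and Gadd45a by 0.79 ± 0.06, while Ank1 fell (−0.50 ± 0.06). Among 20 immediate early genes, 10 rose, 0 fell and 10 did not pass the test (13 up and 1 down adjusted over the list alone, adjusted p = 5.50e-08 by camera, adjusted p = 0.346 with an estimated correlation). Junb, Atf3, Ccn1 and Ier3 rose by 1.09 ± 0.06, 1.62 ± 0.15, 1.83 ± 0.18 and 0.68 ± 0.07. The number of immediate early genes that rose was 6 without mdm mutant 1 and 5 without mdm mutant 2.

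Macrophage markers rose broadly in mdm mutant muscle. Of 33 measured markers, 21 rose, 0 fell and 12 did not pass the test (30 up and 0 down adjusted over the list alone), with a median difference of 0.60 (adjusted p = 1.09e-17 by camera, adjusted p = 0.546 with an estimated correlation). The perforin-like gene Mpeg1 and the Fc receptor genes Fcgr2b and Fcgr3 rose by 1.54 ± 0.15, 0.68 ± 0.06 and 0.72 ± 0.07, beside Lgals3. Of 14 neutrophil markers, 6 rose, 0 fell and 8 did not pass the test (7 up and 0 down adjusted over the list alone, adjusted p = 0.000141 by camera, adjusted p = 0.592 with an estimated correlation), led by S100a8 and S100a9, subunits of calprotectin (2.43 ± 0.26 and 2.08 ± 0.22), and by Camp and Chil3 (0.80 ± 0.13 and 0.93 ± 0.16). The lymphocyte and mast cell lists did not pass. Most of their genes were dim. Without the dimmer probe sets, 3 of 21 lymphocyte and 3 of 12 mast cell genes remained, too few for a list test. The macrophage list kept 24 of 33. The lack of a shift in the lymphocyte and mast cell lists therefore does not show that these cells were unchanged. Of 21 lymphocyte markers, 0 rose, 1 fell and 20 did not pass the test (0 up and 1 down adjusted over the list alone, adjusted p = 0.870 by camera). The gene that fell was Thy1 (−0.43 ± 0.06), while the T cell gene Cd3e differed by −0.16 ± 0.05, Klrd1 by 0.20 ± 0.06 and Il7r by 0.40 ± 0.10 without passing. Of 12 mast cell and eosinophil markers, 0 rose, 0 fell and 12 did not pass the test (0 up and 0 down adjusted over the list alone, adjusted p = 0.639), with differences of −0.16 ± 0.06 for Tpsb2, 0.12 ± 0.06 for Prg2, 0.07 ± 0.06 for Hdc and 0.13 ± 0.13 for Cma1. The number of macrophage markers that rose was 24, 12, 5 and 6 without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, and that of neutrophil markers 9, 6, 0 and 2.

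Among inflammatory mediators some genes rose and others fell. Of 37 cytokine and chemokine genes, 12 rose, 1 fell and 24 did not pass the test (13 up and 2 down adjusted over the list alone, adjusted p = 0.00417 by camera, adjusted p = 0.507 with an estimated correlation). Next to Cxcl10, the chemokines Cx3cl1 and Ccl8 rose by 1.14 ± 0.10 and 0.96 ± 0.14 and the growth factor gene Tgfb2 by 0.65 ± 0.07, while Ccl11 fell (−0.36 ± 0.07). Of 14 complement genes, 4 rose, 2 fell and 8 did not pass the test (8 up and 2 down adjusted over the list alone, adjusted p = 0.00685 by camera, adjusted p = 0.592 with an estimated correlation). C1ra, Serping1, C1qb and C1qa rose (0.71 ± 0.06, 0.58 ± 0.08, 0.77 ± 0.11 and 0.60 ± 0.10), and Clu and Cd59a fell (−0.89 ± 0.14 and −0.41 ± 0.08). Of 17 antigen presentation genes, 4 rose, 0 fell and 13 did not pass the test (6 up and 0 down adjusted over the list alone, adjusted p = 0.00685 by camera, adjusted p = 0.711 with an estimated correlation). Those that rose were the class II genes H2-Eb1, H2-Aa and H2-Ab1 and the invariant chain Cd74, by 0.88 ± 0.16, 1.03 ± 0.21, 0.90 ± 0.19 and 0.92 ± 0.18. Of 22 interferon response genes, 2 rose, 4 fell and 16 did not pass the test (2 up and 6 down adjusted over the list alone, adjusted p = 0.147 by camera). Igtp and Ifitm3 rose (0.75 ± 0.09 and 1.08 ± 0.22), and Gbp2, Xaf1, Iigp1 and Oas2 fell (−0.39 ± 0.07, −0.30 ± 0.06, −0.48 ± 0.09 and −0.30 ± 0.06). The shift of the antigen presentation list did not pass without wild type 2 (adjusted p = 0.177), whereas the interferon list passed as lower without mdm mutant 2 (0.0121) or wild type 2 (0.0120). Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2 the genes that rose numbered 6, 3, 4 and 6 among cytokines, 6, 2, 1 and 2 among complement genes and 6, 3, 0 and 0 among antigen presentation genes, and 0, 0, 0 and 1 interferon genes fell.

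Connective tissue genes rose in part. Of 39 extracellular matrix genes, 11 rose, 1 fell and 27 did not pass the test (17 up and 1 down adjusted over the list alone, adjusted p = 6.32e-05 by camera, adjusted p = 0.351 with an estimated correlation). The proteoglycan genes Bgn and Lum rose by 0.78 ± 0.08 and 0.42 ± 0.05, Fbln2 by 0.55 ± 0.06 and the collagen Col8a1 by 0.94 ± 0.10, while Serpinh1, the collagen chaperone, fell (−0.26 ± 0.06). Of 19 fibroblast and tendon markers only Cilp passed the test (2.69 ± 0.06), with Gsn, Thbs4 and Kera at 0.51 ± 0.13, 0.74 ± 0.20 and −0.88 ± 0.28 (list adjusted p = 0.191 by camera, and 0.0208 without wild type 2). Endothelial markers were lower, with a median of −0.27. Of 16, 0 rose, 2 fell and 14 did not pass the test (0 up and 3 down adjusted over the list alone, adjusted p = 0.00466 by camera, adjusted p = 0.711 with an estimated correlation), and Pecam1 and Robo4 fell (−0.33 ± 0.07 and −0.44 ± 0.10), with Esam at −0.31 ± 0.08 and Cldn5 at −0.77 ± 0.23. That list passed with any mouse left out except mdm mutant 2 (adjusted p = 0.104), and its median was −0.45 without mdm mutant 1 and −0.10 without mdm mutant 2. With the hybridization controls that median was −0.16, and 1 endothelial gene rose and 0 fell in limma. Of 9 Schwann cell markers, 1 rose, 0 fell and 8 did not pass the test (0 up and 0 down adjusted over the list alone, adjusted p = 0.870, median −0.07, mean 0.02), the 1 being Egr2 (0.40 ± 0.09), also an immediate early gene. Drp2, Ugt8a and Pmp22 stood at 0.14 ± 0.06, −0.11 ± 0.06 and 0.10 ± 0.05. Matrix genes that rose numbered 7, 7, 5 and 6, and endothelial genes that fell 8, 0, 0 and 1, without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2.

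The list of 15 adipocyte markers had a median difference of 0.31, although its only gene past the test, Ucp1, fell (adjusted p = 0.0364 by camera, adjusted p = 0.711 with an estimated correlation). Lep, Pparg and Adig stood at 0.31 ± 0.08, 0.34 ± 0.11 and 0.71 ± 0.23. None of the 15 genes passed when adjusted over the list alone. The list did not pass without mdm mutant 1, mdm mutant 2 or wild type 2 (adjusted p = 0.0727, 0.0735 and 0.627). Its median was 0.49 without wild type 1, where 4 genes rose and 1 fell, and 0.09 without wild type 2, where 0 rose and 2 fell. Of 3 measured erythroid genes, too few for a list test, Alas2, an enzyme of haem synthesis, rose (0.92 ± 0.19), and Slc4a1 and Epb42 stood at 1.07 ± 0.30 and 0.13 ± 0.09.

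Partners of titin moved in both directions. Of 33 titin, Z-disc and M-band genes, 7 rose, 5 fell and 21 did not pass the test (8 up and 6 down adjusted over the list alone). Ankrd1, Fhl2 and Fhl1 rose (4.50 ± 0.13, 1.13 ± 0.06 and 0.70 ± 0.10), and the titin-binding protease gene Capn3 fell (−0.82 ± 0.12), as did Tcap, Ankrd23, Fhl3 and Smyd1 (−0.56 ± 0.09, −0.75 ± 0.17, −0.34 ± 0.05 and −0.28 ± 0.06). The list did not pass as a whole (adjusted p = 0.464 by camera), with a median of −0.02 and a mean of 0.26. Sarcoplasmic reticulum calcium genes also moved in both directions. Of 25, 2 rose, 6 fell and 17 did not pass the test (3 up and 8 down adjusted over the list alone), the rises being Sln and the calcium channel subunit Cacng1 (1.01 ± 0.14). The kinase Camk2a and the junctophilin Jph2 fell (−0.62 ± 0.06 and −0.54 ± 0.07). The median of this list was −0.12 and its mean 0.20, and the list did not pass (adjusted p = 0.107). With the hybridization controls 3 of its genes rose and 2 fell, and its median was 0.00. Of 21 dystrophin complex and membrane repair genes, 5 rose, 0 fell and 16 did not pass the test (8 up and 0 down adjusted over the list alone, adjusted p = 0.00754 by camera, adjusted p = 0.432 with an estimated correlation). Those that rose were the annexins Anxa1, Anxa5 and Anxa2 (1.19 ± 0.07, 0.45 ± 0.06 and 0.41 ± 0.08) and the integrins Itga7 and Itgb1 (0.59 ± 0.06 and 0.32 ± 0.06), none of them a member of the dystrophin complex itself. Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, the genes that rose numbered 5, 5, 2 and 4 among titin partners and 5, 2, 2 and 3 in the dystrophin and repair list, while 3, 2, 1 and 1 titin partners and 2, 3, 1 and 2 calcium genes fell.

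Slow fibre contractile genes differed widely between the 2 wild type mice. Of 10 measured, 1 rose, 0 fell and 9 did not pass the test (1 up and 0 down adjusted over the list alone, adjusted p = 0.0447 by camera, adjusted p = 0.713 with an estimated correlation), the gene being Csrp3 (2.46 ± 0.51), a Z-disc protein. Myoz2, Tnni1 and Myh7b stood at 0.96 ± 0.33, 1.93 ± 0.87 and 0.15 ± 0.08. Myh7, the slow myosin heavy chain, named after its values were seen, read 11.62 and 10.40 in the mdm mutant mice and 8.45 and 11.93 in wild type 1 and wild type 2. The median of the list, 0.84 with all mice, was 0.36 without mdm mutant 1, 1.28 without mdm mutant 2, −0.15 without wild type 1 (adjusted p = 0.995) and 1.82 without wild type 2, and the list did not pass without mdm mutant 1 (adjusted p = 0.243). Csrp3 passed in 1 of the 4 fits with a mouse left out, the fit without wild type 2. Of 13 fast fibre genes, 0 rose, 0 fell and 13 did not pass the test (0 up and 0 down adjusted over the list alone, adjusted p = 0.534), with differences of −0.64 ± 0.18 for Mylk2, −0.20 ± 0.08 for Myh4, −0.11 ± 0.06 for Tpm1 and −0.17 ± 0.12 for Myoz1. Actn3, also named after its values were seen, read 14.32 ± 0.11 and 14.27 ± 0.04, close to the top of the array's range at 14.98.

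Genes of energy metabolism were lower in mdm mutant muscle. Of 52 oxidative phosphorylation genes, 0 rose, 8 fell and 44 did not pass the test (0 up and 13 down adjusted over the list alone), with a median of −0.20 and 50 of 52 below 0 (adjusted p = 2.21e-07 by camera, adjusted p = 0.637 with an estimated correlation). Cycs, Ndufs8, Cox7a1 and Ndufa8 fell (−0.41 ± 0.07, −0.48 ± 0.08, −0.61 ± 0.12 and −0.57 ± 0.12). Of 22 citric acid cycle and neighbouring genes, 0 rose, 11 fell and 11 did not pass the test (0 up and 14 down adjusted over the list alone, adjusted p = 1.13e-05 by camera, adjusted p = 0.592 with an estimated correlation). Idh3a, Pdha1, Got1 and Dlat, which encode dehydrogenase subunits, a transaminase and a pyruvate dehydrogenase component, fell (−0.80 ± 0.06, −0.53 ± 0.06, −0.87 ± 0.11 and −0.68 ± 0.10). Of 28 fatty acid genes, 1 rose, 9 fell and 18 did not pass the test (1 up and 18 down adjusted over the list alone), with a median of −0.46 (adjusted p = 1.05e-06 by camera, adjusted p = 0.597 with an estimated correlation). Pdk4, Ucp3 and Acads, a short-chain acyl-CoA dehydrogenase, fell (−2.18 ± 0.23, −1.42 ± 0.10 and −0.50 ± 0.06), and the triglyceride lipase gene Pnpla2 rose (0.48 ± 0.06). Of 19 glycolysis and glycogen genes, 0 rose, 6 fell and 13 did not pass the test (0 up and 10 down adjusted over the list alone, adjusted p = 0.00121 by camera, adjusted p = 0.432 with an estimated correlation). The insulin-regulated glucose transporter Slc2a4, Gpd1 and the phosphorylase kinase subunits Phkg1 and Phka1 fell (−0.61 ± 0.05, −0.87 ± 0.09, −0.64 ± 0.08 and −0.57 ± 0.08). Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2 the genes that fell numbered 11, 0, 0 and 0 in oxidative phosphorylation, 11, 3, 2 and 2 in the citric acid cycle, 14, 3, 3 and 3 in fatty acid use and 3, 5, 2 and 4 in glycolysis. Without mdm mutant 2 the medians were −0.10 in oxidative phosphorylation and −0.28 in fatty acid use, and with the hybridization controls −0.09 and −0.34, with 4 and 9 genes lower. The camera calls of these 4 lists held in each of these fits.

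Stress and protein turnover genes rose in part. Of 30 atrophy and proteolysis genes, 6 rose, 1 fell and 23 did not pass the test (10 up and 2 down adjusted over the list alone, adjusted p = 0.00417 by camera, adjusted p = 0.624 with an estimated correlation). Cdkn1a, the ubiquitin ligase gene Fbxo30 and Gadd45a rose (2.58 ± 0.12, 0.80 ± 0.06 and 0.79 ± 0.06), and Smad3 fell (−0.63 ± 0.06). That list did not pass without wild type 1 (adjusted p = 0.0623). Of 22 heat shock and stress genes, 8 rose, 2 fell and 12 did not pass the test (11 up and 3 down adjusted over the list alone, adjusted p = 0.00196 by camera, adjusted p = 0.546 with an estimated correlation). The small heat shock protein gene Hspb8 and the chaperone Hspa5 rose (0.98 ± 0.11 and 0.31 ± 0.05), while Hspb6 and the mitochondrial superoxide dismutase Sod2 fell (−0.47 ± 0.06 and −0.50 ± 0.08). Of 29 cell cycle genes, 1 rose, 0 fell and 28 did not pass the test (1 up and 0 down adjusted over the list alone, adjusted p = 0.0162 by camera, adjusted p = 0.757 with an estimated correlation), the rise being the replication gene Mcm6 (0.98 ± 0.08), with Aurka, Ccne1 and Rrm2 at −0.48 ± 0.12, 0.24 ± 0.06 and 0.75 ± 0.22. That list did not pass without mdm mutant 2 (adjusted p = 0.758) or wild type 2 (0.488). Of 16 circadian clock genes, 2 rose, 2 fell and 12 did not pass the test (3 up and 4 down adjusted over the list alone, adjusted p = 0.668). Nr1d1 and Nr1d2 fell (−0.37 ± 0.05 and −0.27 ± 0.06) and Per2 and Hlf rose (0.47 ± 0.10 and 0.27 ± 0.05). Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, heat shock genes that rose numbered 1, 3, 1 and 1, atrophy genes 7, 4, 3 and 5, cell cycle genes 4, 1, 1 and 1 and clock genes 0, 0, 0 and 2, and 1, 0, 0 and 0 clock genes fell.

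**Figure D2:**
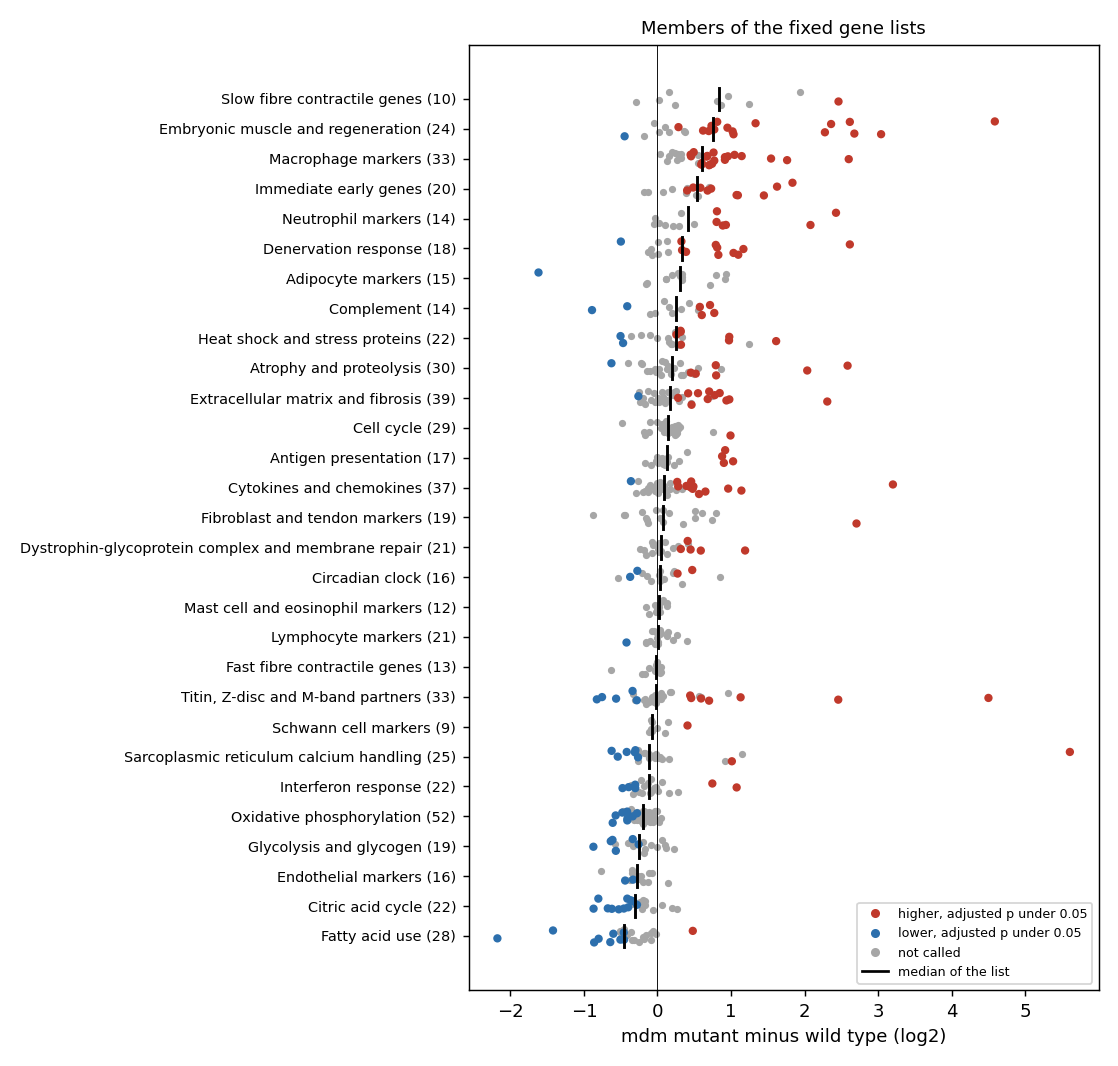
Differences of the members of the 29 gene lists tested, with mdm mutant minus wild type (log2) on the horizontal axis and each dot 1 gene. Red and blue dots passed the test as higher or lower, grey dots did not, and black bars are list medians, such as 0.75 for embryonic muscle genes.

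Sex-linked genes differed within the wild type group. Xist, the RNA that silences an X chromosome in females, read 9.98 in wild type 2 and between 6.17 and 6.23 in the other mice. The Y-linked genes Eif2s3y and Uty read 5.88 and 5.97 in wild type 2 and at least 9.28 and 6.86 in the others, while Usp9y lay between 6.28 and 6.46 in all 4. This pattern is that of a female in wild type 2 and of males in the other 3 mice, and none of these genes passed the test between groups. Without wild type 2, 516 probe sets were called among the 3 mice of male pattern, and 460 of them belonged to the 2115.

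**Figure D3:**
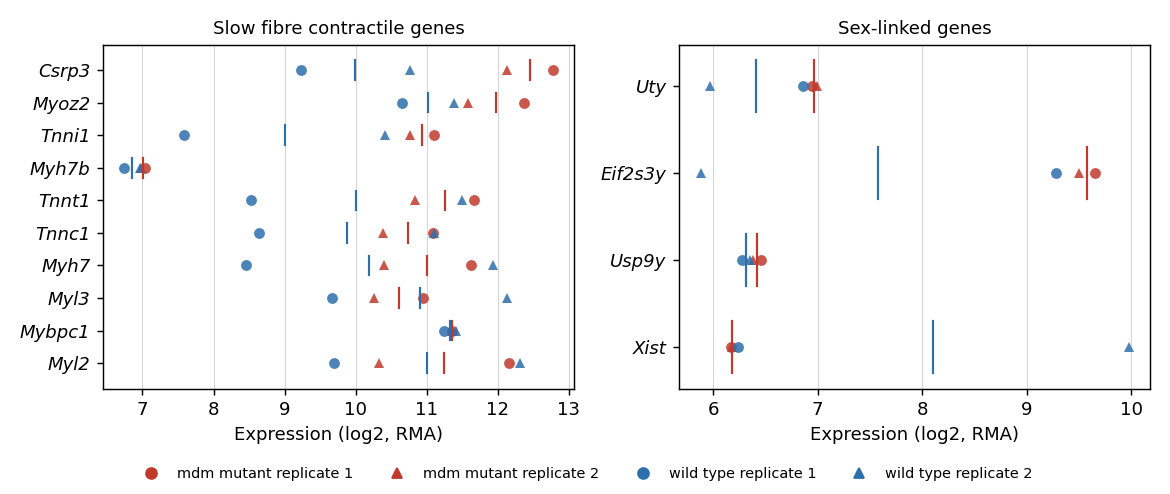
Expression of slow fibre contractile genes (left) and sex-linked genes (right), with the log2 RMA value on the horizontal axis, each symbol 1 mouse and each vertical bar a group mean. Wild type 1 has the lowest value of Myh7 (8.45) and wild type 2 the highest value of Xist (9.98).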

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

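Centring on the hybridization controls was chosen after the data were seen. All other settings were planned. The count stayed between 1827 and 2335 without the dimmer probe sets, with repeated centring or quantile normalization, with trend and robust on and with probe sets averaged. It moved elsewhere. With each mouse left out in turn it ranged from 490 to 1182 (287 to 637 higher, 186 to 545 lower), with fewer samples in the fit, and 963, 529, 430 and 460 of the 2115 stayed called without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2. Without variance moderation 1 probe set passed in limma (0 higher, 1 lower), and 3286 had an unadjusted p under 0.05. That probe set, Slc25a4, had equal values within each group and was not called in the main fit (adjusted p = 0.108 in limma). Thus 0 of the 2115 stayed called, and the difference of Sln stayed 5.61 without passing. With the hybridization controls 3432 were called (2829 higher, 603 lower), and the list medians of titin partners, fast fibre genes and Schwann cell markers turned from below to above 0. Counts of genes that rose changed from 5 to 10 for dystrophin and repair, 4 to 8 for complement, 4 to 7 for antigen presentation, 11 to 17 for matrix, 6 to 10 for atrophy, 8 to 14 for heat shock, 1 to 4 for cell cycle, 2 to 4 for the clock, 1 to 3 for Schwann cell and for fibroblast markers, 0 to 3 for lymphocyte, 0 to 2 for adipocyte and 0 to 1 for mast cell markers. Those that fell changed from 6 to 2 for calcium handling, 8 to 4 for oxidative phosphorylation, 5 to 3 for titin partners, 4 to 2 for interferon and 2 to 0 for endothelial markers. At an adjusted p under 0.10 the count was 3719 (1800 higher, 1919 lower), at 0.01 it was 304 (183 and 121), and with a 2-fold minimum 119 (89 and 30).

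With the planned preset correlation 20 of 29 lists passed. With an estimated correlation 0 passed (15 to 20 did under the other camera settings), with adjusted p of 0.713 for slow fibre genes, 0.346 for embryonic muscle, 0.351 for denervation, 0.546 for macrophages, 0.592 for neutrophils, 0.507 for cytokines, 0.592 for complement, 0.711 for antigen presentation, 0.351 for matrix, 0.711 for endothelial markers, 0.711 for adipocyte markers, 0.624 for atrophy, 0.546 for heat shock, 0.637 for oxidative phosphorylation, 0.592 for the citric acid cycle, 0.432 for glycolysis, 0.597 for fatty acids, 0.432 for dystrophin and repair, 0.757 for cell cycle and 0.346 for immediate early genes. With fry, which tests each list by itself, 6 passed. Of the 20 lists that passed with the preset correlation, those that did not pass fry were slow fibre genes (0.664), macrophages (0.103), neutrophils (0.186), cytokines (0.103), complement (0.187), antigen presentation (0.591), endothelial markers (0.309), adipocyte markers (0.612), atrophy (0.187), heat shock (0.127), oxidative phosphorylation (0.187), citric acid cycle (0.127), fatty acids (0.178) and cell cycle (0.664).

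Without the dimmer probe sets slow fibre genes (0.117), complement (0.0681), adipocyte markers (0.117) and cell cycle (0.158) no longer passed. Without genes of more than 1 list, slow fibre genes (0.194) and complement (0.114) did not. With the hybridization controls slow fibre genes (0.560), complement (0.139), antigen presentation (0.0789), adipocyte markers (0.560), atrophy (0.103), heat shock (0.0681) and cell cycle (0.374) did not pass, while calcium handling (0.0257) and interferon (0.0215) passed as lower relative to the other genes. The medians of the calcium and interferon lists were then −0.004 and −0.007, and in each of them 3 genes rose and 2 fell. With each mouse left out in turn, adjusted p ranged from 3.94e-07 to 0.995 for slow fibre genes, 3.40e-06 to 0.627 for adipocyte markers, 0.0120 to 0.798 for interferon, 8.96e-07 to 0.104 for endothelial markers, 7.12e-06 to 0.758 for cell cycle, 0.000133 to 0.0623 for atrophy, 2.48e-05 to 0.177 for antigen presentation and 0.0208 to 0.995 for fibroblast markers. Apart from the smaller samples, the cause of these changes was not tested. Of the genes named singly, 26, 52, 69 and 62 calls were lost without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, 137 without variance moderation, 8 with trend and robust on and 11 with the hybridization controls. Signal over background cannot be judged from these values.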

Other observations

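The tests of gene families grouped by symbol, the count of other splits of the arrays, the count of calls without a wild type mouse, the ratio of the 2 wild types over probe sets picked without wild type 1 and the 3' to 5' signal of 2 further control genes were chosen only after the results were seen. More families were tested than are described below. Of the others, homeobox, mitochondrial carrier and histone genes passed as lower by camera (adjusted p = 0.00284, 0.0409 and 0.0488). With an estimated correlation none of them passed (adjusted p = 0.417 each), and their medians turned above 0 with the hybridization controls. Mitochondrial ribosomal protein genes fell together: of 71 measured, 0 rose and 24 fell, with a median difference of −0.24 (adjusted p = 2.14e-11 by camera, adjusted p = 0.417 with an estimated correlation). Mrps27 and Mrps28 fell (−0.46 ± 0.06 and −0.61 ± 0.08). Genes named as proteins of the cytosolic ribosome went the other way, with 7 of 23 higher and 1 lower, among them Rps9 (0.54 ± 0.07) and Rpl23 (0.37 ± 0.05), and with the muscle paralogue Rpl3l lower at −0.67 ± 0.05 (adjusted p = 6.62e-06 by camera, adjusted p = 0.417 with an estimated correlation). Genes named as proteasome subunits had 7 of 34 higher and 1 lower (adjusted p = 3.12e-06 by camera, adjusted p = 0.417 with an estimated correlation), with Psmd11 at 0.52 ± 0.07 and Psmd9, the gene that fell, at −0.24 ± 0.05. With the arrays centred on the hybridization controls the medians of these 3 families were −0.12, 0.41 and 0.33 in place of −0.24, 0.30 and 0.22, and 15 mitochondrial ribosomal genes fell while 17 cytosolic ribosomal and 21 proteasome genes rose, with 0 proteasome genes lower. Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, 18, 2, 0 and 0 mitochondrial ribosomal genes fell, while 5, 1, 0 and 0 cytosolic ribosomal and 7, 1, 2 and 0 proteasome genes rose, and no proteasome gene fell in any of these limma fits.

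Among 10 tubulins 3 rose and 3 fell (adjusted p = 0.535 by camera, adjusted p = 0.608 with an estimated correlation): Tubb6, Tubb2a and Tubb5 rose by 2.12 ± 0.11, 1.30 ± 0.09 and 0.68 ± 0.10, and Tuba8, Tuba4a and Tubg1 fell (−0.97 ± 0.12, −0.44 ± 0.06 and −0.26 ± 0.05). The partner keratins Krt18 and Krt8 were the 2 of 38 keratins that rose (2.08 ± 0.16 and 1.07 ± 0.09). Of 11 annexins 5 rose (adjusted p = 0.00327 by camera, adjusted p = 0.417 with an estimated correlation), Anxa4 by 0.85 ± 0.09. Of 14 S100 genes 5 rose, S100a4 by 1.58 ± 0.15, and S100a1, abundant in muscle, fell (−0.36 ± 0.06). Of 64 potassium channel genes 10 fell, among them Kcna7 (−0.72 ± 0.07) and Kcnc1 (−0.64 ± 0.06), and 1, Kcne1l, rose (0.67 ± 0.15), with a family median of −0.05 that turned to 0.06 with the hybridization controls, where 5 rose and 7 fell. With those controls 4 tubulins rose and 2 fell, and 6 annexins, 7 S100 genes and 2 keratins rose. Without mdm mutant 1, mdm mutant 2, wild type 1 and wild type 2, 2, 1, 0 and 0 tubulins and 3, 2, 5 and 4 potassium channel genes fell, while 3, 2, 3 and 2 tubulins, 6, 3, 1 and 1 annexins and 5, 4, 1 and 4 S100 genes rose. No S100 gene fell and no potassium channel gene rose in any of these limma fits.

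The difference between the groups was large next to that within them. The SD of the difference between arrays over probe sets was 0.140 for the mdm mutant pair, 0.155 for the wild type pair and 0.271 to 0.298 between groups. Of the 3 splits of the 4 arrays into pairs, 1, the real one, gave as many calls: it called 2115 probe sets in limma, and the others called 0 each, with 94 and 93 at an unadjusted p under 0.05. With 3 splits no share under 0.05 can be reached. The other splits each put a mutant and a wild type mouse in 1 group, so the difference between genotypes enters their residual spread. Their counts are therefore no reference for chance, and the splits decide nothing about it. The sex of wild type 2 as the cause is argued against by wild type 1, which shares the male pattern of the mutants. Over 3975 probe sets picked without wild type 1 (unadjusted p under 0.05), which hold all 2115 calls, its difference from the mutants had a median of 0.857 of that of wild type 2 (quartiles 0.606 and 1.08), where the mutants shared by both differences would alone give 0.333. Without wild type 2, 516 probe sets were called, 1.05 times the 490 called without wild type 1, while the planned ratio of the difference without wild type 2 to that with it (median 0.995 over the 2115, smallest 0.651) was bounded by the calls and decides nothing by itself. RNA degradation cannot be told apart: the 3' minus 5' signal of control probe sets was higher in mdm mutant mice by 0.30 for the transferrin receptor and 0.14 for Actb on the log2 scale, with no overlap of the groups, and by 0.18 for pyruvate carboxylase and 0.02 for Gapdh, with overlap. The planned bound of 0.25 was set for Actb and Gapdh alone and is exceeded by the transferrin receptor. The 5' probe set of that gene read 6.21 in mdm mutant and 6.63 in wild type mice on average. Both lie below the array median of 7.28, so its difference is a weak measure of RNA integrity. The titin genotype remains as a hypothesis, next to other differences between the animals, which were not tested.

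The rise of macrophage markers may reflect more macrophages or higher expression in them, which these data do not separate. A lower share of muscle fibre RNA alone would raise the markers of all other cell types alike, if those cells did not themselves change. The macrophage median (0.60) exceeded the Schwann cell median by 0.67 and the endothelial median by 0.88. The endothelial list was itself lower, so that comparison does not meet this condition. The Schwann cell list rested on 9 genes, of which 5 remained without the dimmer probe sets. Whether Schwann cells themselves changed was not tested. Other non-fibre lists had medians of 0.01 for lymphocytes, 0.02 for mast cells, 0.07 for fibroblasts, 0.31 for adipocytes and 0.41 for neutrophils. The lists did not rise alike, as a lower fibre share with all other cells unchanged would require. Since that condition was not tested, the comparison cannot decide whether a lower fibre share gave the rise. The macrophage, Schwann cell and endothelial medians were 0.73, −0.03 and −0.45 without mdm mutant 1 and 0.48, −0.06 and −0.10 without mdm mutant 2. In a 2-sided permutation test over genes, which are not independent, p was 8e-05 and 1e-05 (0.000107 and 2e-05 adjusted over 4 such comparisons), 1e-05 being the smallest that 100000 resamples can give. Blood left in the tissue cannot be told apart: the median of the erythroid list was 0.92, above the macrophage median of 0.60, which was the planned sign of blood. That median rested on 3 genes, fewer than the minimum of 5. It was 0.62 without mdm mutant 1, 0.59 without mdm mutant 2, 0.98 without wild type 1 and 0.86 without wild type 2. Blood as a source of the rise of neutrophil markers was not tested. The marker Lyz2, named after its values were seen, read 11.36 ± 0.27 in mdm mutant and 10.22 ± 0.11 in wild type mice, and 3 of the 33 genes also belong to another list.

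Genes near titin could carry sequence of the strain in which the mutation arose. Of the 100 measured genes nearest to Ttn in gene order 18 were called, against 1975 of the 15167 other named genes (odds ratio 1.47, 95% interval 0.826 to 2.47, Fisher's exact test, 2-sided, p = 0.138). Among the 18 were Chrna1 and Serping1, named above in the denervation and complement lists. That explanation for the 18 genes cannot be told apart from an effect of the mutation, since the interval holds both no excess and a 2-fold one.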
